A study of Homo sapiens with 12 samples.

How the data were processed

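Gene expression was measured on Affymetrix U133 Plus 2.0 arrays, on which each gene is read by 1 or more sets of short probes. Per the labels, Ishikawa cells, an established line of endometrial adenocarcinoma origin, were transfected for 48 h with a negative control siRNA or an siRNA against GPR54, and then received 10 µM metastin-10 or a control peptide for 24 h. The 12 arrays form 4 groups of 3, and the labels call the 3 biological replicates. Total RNA was prepared on Qiagen columns and labelled by Affymetrix one-cycle in vitro transcription, per the labels' protocols.

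The authors deposited 1 table of log2 values, made with RMA per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a set by median polish. The software and its version are not given in the sources used here. The values ran from 1.88 to 14.6, and the array medians from 5.13 to 5.22 on the log2 scale. Scanner files and detection calls were not used here, so the background level is unknown and a fold change of a dim probe set may be compressed. RMA forces the arrays to a common distribution, so a shift of most genes in one direction would not be seen. For arrays, precision is limited by their number. Over all probe sets the median half-width of the 95% interval of a log2 fold change was 0.25.

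The table held 54675 probe sets. The 62 control probe sets were left out of the tests, and 54613 were tested with no filter on level. Probe sets were named through the annotation of the array platform, and symbols were looked up by Entrez identifier in the gene table of assembly GRCh38.p14, which changed 0 of the 41043 matched. Of the tested probe sets, 41091 had 1 gene and 1801 had several, and those with several were not named. The remaining 11721 (21.5%) were not listed in the gene annotation used and are unnamed here, which does not mean that they read no gene. Where a gene had several probe sets, the brightest by its mean over the 12 arrays stood for it, which gave 19775 genes. No coordinates are given, since the values carry no genome build.

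Each probe set was fitted with limma 3.58.1 in R 4.3.3 as 4 group means over all 12 arrays, with 8 residual degrees of freedom and empirical Bayes moderation. There were 5 contrasts: metastin-10 against control peptide under each siRNA, the siRNA against control siRNA under each peptide, and the interaction, which is the metastin-10 effect under GPR54 siRNA minus that under control siRNA. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 54613 probe sets of a contrast with a threshold of 0.05. The adjusted p given for a gene comes from this limma fit unless another is named. An exact permutation test over the 924 splits of 6 against 6 arrays compared the targeted gene between the siRNAs without regard to the peptide. On simulated data for the metastin-10 contrast under control siRNA over 54613 probe sets, 95% of log2 changes of 1 and 24% of log2 changes of 0.5 were recovered, and 4 of 123 calls were false.

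The gene lists were fixed before the data were examined. The 26 lists held 580 entries, of which 540 were measured. They were kisspeptin receptor signalling, immediate early and MAPK feedback, matrix proteases and inhibitors, epithelial junction and keratin, mesenchymal transition, adhesion and motility, S phase, G2 and mitosis, p53 targets, apoptosis regulators, NF-kB and inflammation, interferon response, cholesterol synthesis and LDL uptake, unfolded protein and amino acid stress, hypoxia and glycolysis, TGF-beta targets, oestrogen and progesterone response, angiogenesis factors, metallothioneins, oxidative phosphorylation, cytosolic ribosomal proteins, RNA interference machinery, and markers of stromal fibroblasts, endothelium, leukocytes and smooth muscle. Each was tested with camera at a preset correlation of 0.01 and adjusted over the 26 lists of a contrast. Camera with an estimated correlation and fry were alternatives. Camera compares a list with the other genes, while fry tests whether its genes move on balance one way.

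Named genes follow a rule fixed at the same time. It takes KISS1R and KISS1, then per contrast the 12 highest and 12 lowest genes past the threshold whose 2 groups do not overlap (for the interaction, past the threshold only), or the 5 genes with the smallest p where none passed. It also takes up to 4 members of each list past the threshold, or at most 2 with the smallest p. Genes named outside the rule are said to be chosen after their values were seen.

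The labels number the replicates 1 to 3 in each group and do not say that a number is shared between groups. The deviations of same-numbered arrays from their group means correlated by over 0.1 for all 3 pairs of metastin-10 against control peptide under control siRNA (0.17 to 0.44), of the same comparison in the arrays labelled GPR54 siRNA (0.26 to 0.52) and of the siRNA labels with control peptide (0.11 to 0.54). The numbers were therefore taken to pair the arrays of these 3 comparisons, a pairing that comes from the values and was settled after the calls of both fits were known. A shift shared by the replicate 3 arrays alone could also raise all 3 correlations, so the values do not show that numbers 1 and 2 pair. The counts, standard errors, intervals and adjusted p given come from the fit without the replicate block unless the block is named. For the 3 comparisons taken as paired they therefore leave the pairing out. For the siRNA labels with metastin-10 the correlations were -0.15, 0.26 and 0.07, so the numbers were not taken to pair that comparison. They were not taken to pair the interaction, which uses all 4 groups, either. However, the 3 comparisons taken as paired link all 4 groups. If a number stood for arrays prepared together, it would pair the siRNA labels with metastin-10 and the interaction too. The values do not settle this, so those 2 contrasts are given with the block as well. The alternatives fixed before the data were examined were the replicate number as a block, leaving out each array, only the probe sets above percentile 50 or above percentile 75 of mean level, a further quantile normalization, centring on array medians, a trended and robust prior, array weights, a fit of only the 2 groups compared, 1 probe set per gene, and a minimum of 2-fold. Replicate 3 as a batch block, replicates 1 and 2 only, and the level of the poly-A spikes as a covariate were added after seeing the data. The poly-A spikes are control transcripts added before labelling, and the difference between the 3 prime and 5 prime beta-actin control probe sets reflects how complete the labelled RNA is.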

Results

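Expression was profiled in Ishikawa endometrial cancer cells under a combination of an siRNA and a peptide. Metastin-10, also called kisspeptin-10, is the short C-terminal peptide of the KISS1 product, and its receptor GPR54 is the product of KISS1R. The design addressed which genes change with metastin-10 and whether they do so through that receptor. There were 12 arrays in 4 groups of 3: control siRNA with control peptide, control siRNA with metastin-10, GPR54 siRNA with control peptide, and GPR54 siRNA with metastin-10. All arrays correlated with each other at between 0.992 and 0.998 over the probe sets, and the smallest SD of the difference between 2 arrays was 0.15 on the log2 scale, so no array was a copy of another. The replicate 3 arrays of all 4 groups stood apart in their controls and over the tested probe sets. Their 5 prime poly-A spike level averaged 8.54 ± 0.08 (log2, SD over 4 arrays), against 8.05 ± 0.22 for replicate 1 and 7.69 ± 0.15 for replicate 2. Their beta-actin 3 prime minus 5 prime difference was 0.31 ± 0.04, against 0.77 ± 0.09 and 0.72 ± 0.05. On the largest axis of variation between arrays (principal component 1, 27.7% of variance) the replicate 3 arrays lay between 0.24 and 0.51. The other arrays lay between -0.37 and 0.20 there. Replicate 3 was present once in each group, so these differences did not follow the groups. Replicates 1 and 2 of control siRNA with metastin-10 lay at 0.66 and 0.46 on the second-largest axis of variation between arrays (principal component 2, 21.4% of variance). The other arrays, replicate 3 of that group at -0.25 included, lay between -0.30 and 0.17 there. The poly-A spike levels of those 2 arrays, 7.73 and 7.49, were the lowest of their replicate numbers.

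KISS1R, the gene targeted by the GPR54 siRNA, was not lower in the arrays labelled GPR54 siRNA. Its probe set averaged 9.28 ± 0.13 (log2, SD, n = 3) with control siRNA and control peptide, and 9.42 ± 0.05 and 9.43 ± 0.16 in the arrays labelled GPR54 siRNA with control peptide and with metastin-10. The group that stood apart was control siRNA with metastin-10, at 8.40 ± 0.04. With control peptide, the arrays labelled GPR54 siRNA lay 0.14 above control siRNA (95% interval -0.07 to 0.35), so a fall of the mRNA was not seen at this probe set. Over both peptides the 6 arrays labelled GPR54 siRNA averaged 9.43 ± 0.11 and the 6 control siRNA arrays 8.84 ± 0.49, a difference of 0.59 with a two-sided exact permutation p of 0.013, in the direction opposite to a knockdown. This test ignores the peptide, and the 6 control siRNA arrays join groups at 9.28 and 8.40. The difference therefore comes mostly from the control siRNA, metastin-10 group and does not show an effect of the siRNA label alone. The position of the siRNA target relative to this probe set is not known here. KISS1, which encodes the ligand precursor, was at 4.24 ± 0.08 (SD) over the 6 control siRNA arrays and 4.23 ± 0.08 over the 6 others. Because the targeted gene was not lower there, the 2 groups are called the arrays labelled GPR54 siRNA from here on.

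**Figure D1:**
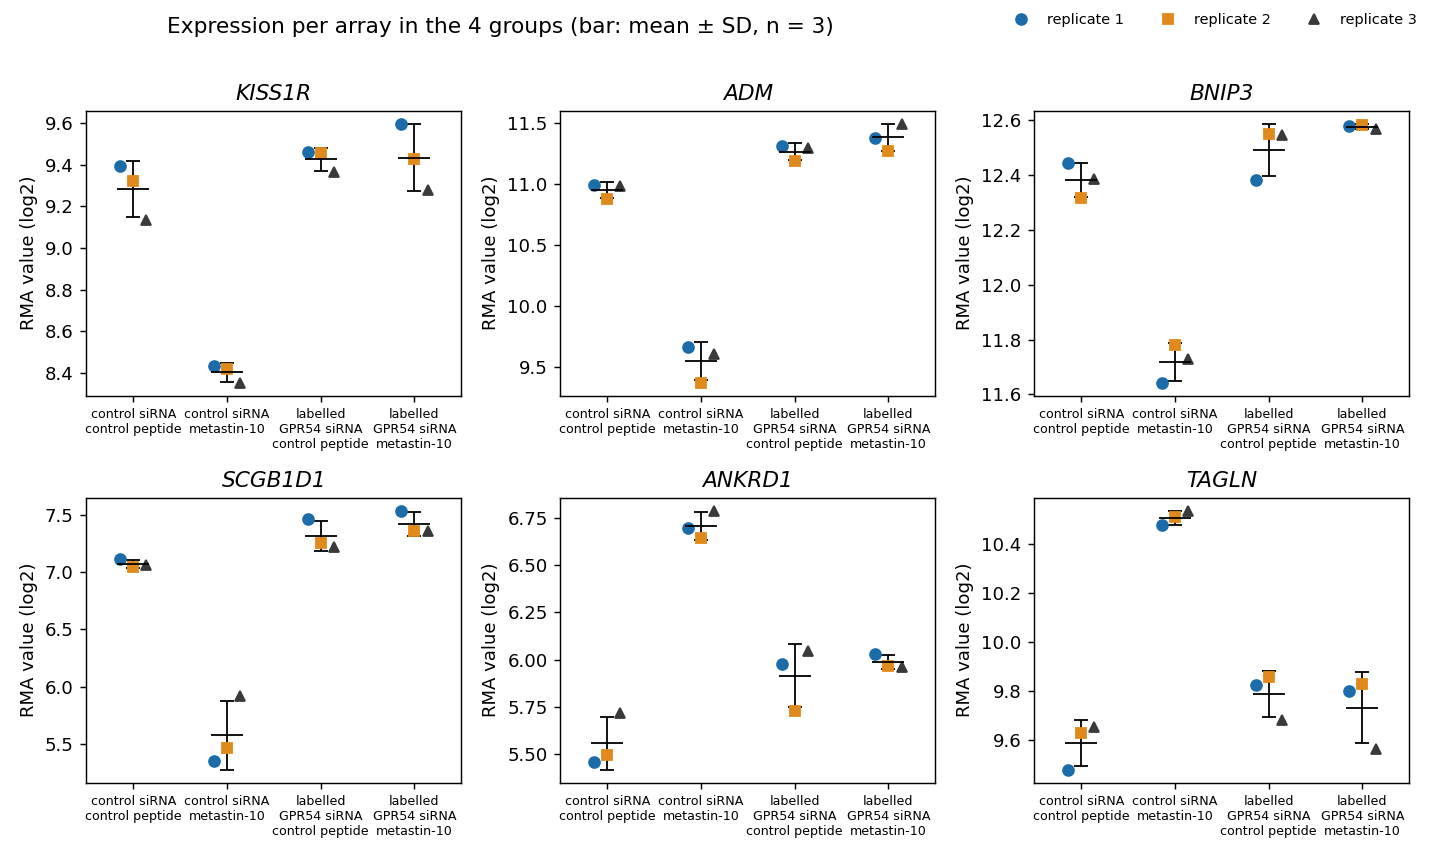
RMA log2 values per array of KISS1R, ADM, BNIP3, SCGB1D1, ANKRD1 and TAGLN in the 4 groups, with symbols for the replicate number and a bar for the mean ± SD (n = 3). The control siRNA, metastin-10 arrays lie apart from the other 3 groups for each of the 6 genes, and KISS1R there averages 8.40 against 9.28, 9.42 and 9.43 elsewhere.

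Under control siRNA, many more genes were lower than higher with metastin-10. The genes with the lowest values included SCGB1D1, a secretoglobin (2.82-fold lower, log2 -1.50 ± 0.13 SE), and ADM, which encodes the vasodilator peptide adrenomedullin (2.65-fold lower, -1.41 ± 0.10). COXFA4L2, a mitochondrial protein induced by hypoxia, was lower by -1.31 ± 0.14 and the cytochrome P450 gene CYP1A1 by -1.08 ± 0.09. At the other end were ANKRD1, an ankyrin repeat protein (2.23-fold higher, 1.15 ± 0.10), and TAGLN, an actin-binding protein of contractile cells (1.90-fold higher, 0.92 ± 0.09). KISS1R itself fell 1.84-fold (-0.88, 95% interval -1.09 to -0.67, adjusted p = 0.00213). In all, 234 probe sets passed, 23 higher and 211 lower, which came to 15 genes higher and 105 lower at 1 probe set per gene.

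The other lowest genes were SPAG4 (-1.05), G0S2, an inhibitor of triglyceride lipase (-1.01), the matrix protease MMP10 (-0.97), DPYSL4 (-0.96), the cilia-associated genes DNAI7 (-0.91) and CFAP96 (-0.90), and the collagen gene COL5A2 (-0.88). Of DPYSL4, the other 2 probe sets were at -0.08 and 0.14 and did not pass. The other highest genes were the protease ADAMTS5 (0.91), CCN2, which encodes connective tissue growth factor (0.74), the potassium channels KCNJ2 (0.72) and KCNJ16 (0.67), the ERBB ligand NRG1 (0.71), the transcription factor CREB5 (0.62), MYEOV (0.61), AMIGO2 (0.61), the tight junction gene CLDN1 (0.58) and SAMD4A (0.55). Of NRG1, the other probe sets lay between -0.003 and 0.28 and did not pass. Of CREB5, a further probe set at 0.57 passed, while those at -0.005 and 0.25 did not. Over the genes named highest or lowest in the pairwise comparisons, 16 had other probe sets, 34 in all. Of these 29 had the same sign, 6 of them past the threshold, and none passed with the other sign.

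Hypoxia and glycolysis genes fell together with metastin-10 under control siRNA. Of the 27 measured members, 10 fell and 0 rose over all probe sets, 17 fell adjusted over the list alone, and all 27 lay below 0, with a median of -0.39. ADM was the lowest. The aldolase gene ALDOC was at -0.87 ± 0.08, ANKRD37 at -0.79 ± 0.10, and VEGFA, the vascular growth factor, at -0.74 ± 0.11. Camera called the list lower (adjusted p = 2.83e-24, and adjusted p = 0.00304 with an estimated correlation). Between same-numbered arrays the list median was -0.46, -0.39 and -0.31 for replicates 1, 2 and 3.

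**Figure D2:**
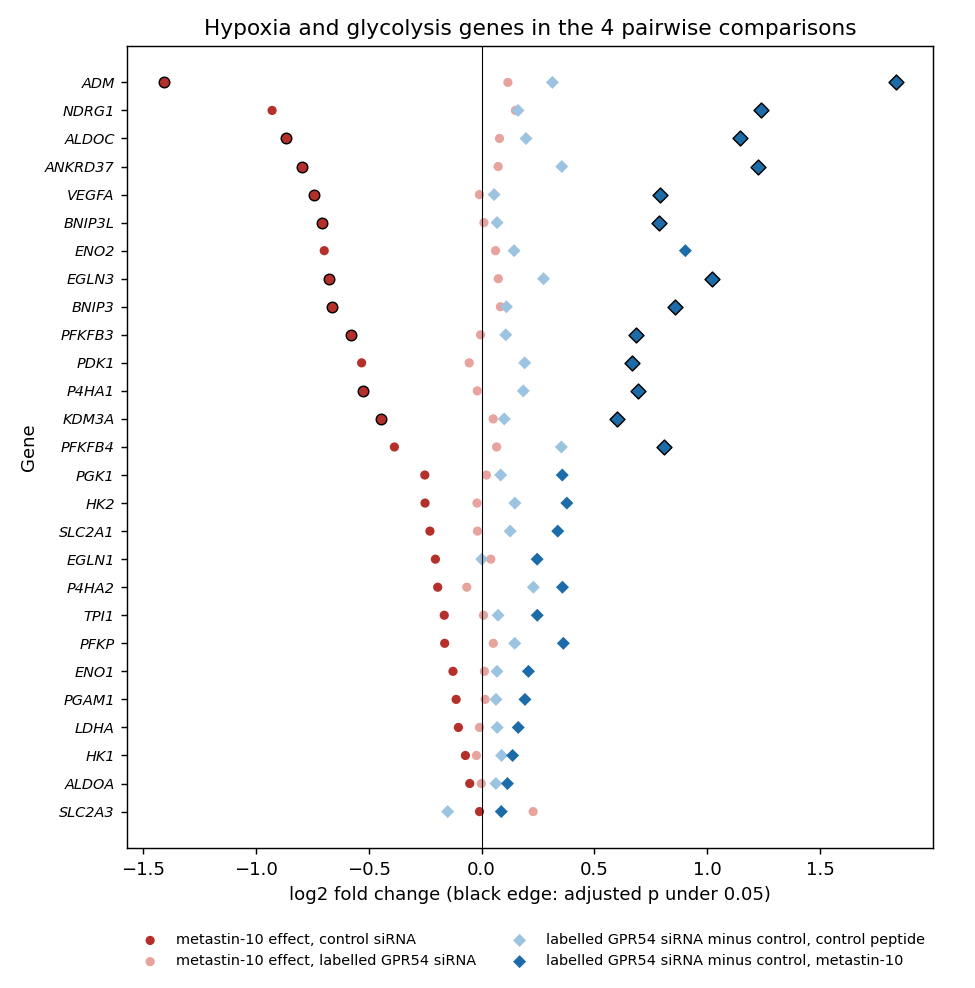
Log2 fold changes of the 27 hypoxia and glycolysis genes, 1 row per gene, in the 4 pairwise comparisons (circles, metastin-10 effects, and diamonds, siRNA label effects; a black edge marks an adjusted p under 0.05). The metastin-10 effect under control siRNA has a median of -0.39 and the difference between the siRNA labels with metastin-10 a median of 0.60, while in the arrays labelled GPR54 siRNA the metastin-10 effect has a median of 0.02.

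Camera called 3 other lists under control siRNA, none of which kept its call with an estimated correlation. The epithelial junction and keratin list (22 genes) had a median of -0.15, with KRT19 lower (-0.48) and CLDN1 higher (adjusted p = 0.00198, and adjusted p = 0.564 with an estimated correlation). The unfolded protein and amino acid stress list (27 genes) had a median of -0.09, and the member that fell, VLDLR (-0.56), is a lipoprotein receptor (adjusted p = 0.0167, and 0.564 as the adjusted p with an estimated correlation). The 6 smooth muscle markers had a median of 0.17 and only TAGLN rose (adjusted p = 0.00873, and adjusted p = 0.127 with an estimated correlation). Adjusted over the list alone, these 3 lists in turn had 1 higher and 2 lower, 0 higher and 3 lower, and 1 higher and 0 lower members.

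Some lists held single called members without a call of the list. The chemokine receptor gene CXCR4 fell (-0.88) among 32 adhesion and motility genes (list median 0.03), and S100A4 (-0.44) among 20 mesenchymal transition genes (-0.08). STC2 fell (-0.77) among 22 oestrogen and progesterone response genes (-0.09), and PTGS2, which encodes cyclooxygenase-2, fell (-0.50) among 22 NF-kB and inflammatory genes (0.10). Among 26 matrix protease and inhibitor genes (median 0.01, mean -0.0087) MMP10 fell and ADAMTS1 (0.47) rose. CCN2 was the member that rose among 27 immediate early and MAPK feedback genes (median 0.01) and among 20 TGF-beta targets (-0.03). VEGFA was the member that fell among 19 angiogenesis factors (0.08) and KISS1R among 19 kisspeptin receptor signalling genes (-0.03). Adjusted over the list alone, 6 immediate early genes rose and 1 fell, 3 mesenchymal transition and 2 NF-kB genes fell, 1 adhesion and 1 kisspeptin signalling gene fell, and 1 rose and 1 fell in each of the matrix protease, TGF-beta, oestrogen and angiogenesis lists.

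No member was called in the S phase (29 genes, median -0.0018), G2 and mitosis (30, -0.02), p53 target (21, -0.09), apoptosis (19, -0.07), interferon (31, -0.04), cholesterol (19, -0.00079), metallothionein (9, 0.02), oxidative phosphorylation (26, -0.03), ribosomal protein (25, -0.02) or RNA interference (14, -0.04) lists. Adjusted over the list alone, 1 p53 target rose and 3 fell, 2 apoptosis regulators and 1 interferon gene fell, and the other lists named here had 0. The S phase and cholesterol lists had medians below 0 and means above 0 (0.0073 and 0.0061). The stromal fibroblast (10 genes, 0.10), endothelial (9, 0.10) and leukocyte (9, 0.14) markers had no called member either, also adjusted over the list alone. Camera called none of these lists nor those with single called members, but the p53 list was called with the replicate block (adjusted p = 0.0446, against an adjusted p of 0.564 with an estimated correlation and no block), as was the apoptosis regulator BMF (-0.50, adjusted p = 0.0166). For the interferon, p53, S phase and cholesterol lists the smallest p belonged to DDX60 (-0.37, adjusted p = 0.084), CDKN1A (-0.40, adjusted p = 0.0643), CDT1 (-0.24, adjusted p = 0.476) and ACAT2 (0.20, adjusted p = 0.405).

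The number of calls for metastin-10 under control siRNA moved with the fit. It was 422 with the replicate block, 532 with replicate 3 as a batch block, 179 with replicates 1 and 2 only, and 77 with only the 2 groups compared. Leaving out replicate 1 or 2 of the metastin-10 group left 85 and 103, while leaving out replicate 1, 2 or 3 of the control peptide group left 87, 71 and 131.

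In the arrays labelled GPR54 siRNA, metastin-10 changed no probe set past the threshold. The genes lower with metastin-10 under control siRNA, 105 in number, had a median log2 difference of 0.02 there, and the 15 higher genes a median of -0.04. ADM was at 0.12 (95% interval -0.09 to 0.33), BNIP3 at 0.08 (-0.09 to 0.26) and VEGFA at -0.01 (-0.24 to 0.23), and KISS1R was at 0.01 (-0.20 to 0.22). The hypoxia and glycolysis list had a median of 0.02 with 0 members called, also adjusted over the list alone, and none of the 26 lists was called by camera (smallest adjusted p = 0.212, and 0.914 as the smallest adjusted p with an estimated correlation).

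The limma fit gave 0 probe sets with a smallest adjusted p of 0.999997. At an unadjusted p under 0.05 there were 1206 probe sets, against 2731 expected by chance. There were 1705 with the replicate block and 4818 with array weights, and in both the count past the threshold was also 0. The count was also 0 with replicate 3 as a batch block and with replicates 1 and 2 only. The 5 genes with the smallest p, none of which passed, were PIP5K1B (-0.55), LINC01213 (-0.31), MS4A7 (0.43), MYOT (-0.31) and GPR183 (0.35). Across the 19775 genes, which are not independent replicates, the metastin-10 effects under the 2 siRNA labels, which share no arrays, correlated at Pearson r = 0.07 and Spearman rho = 0.08.

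With control peptide, the arrays labelled GPR54 siRNA differed from control siRNA by 29 lower probe sets and 0 higher. Of the 29, 24 have no gene in the annotation used, 1 has several and 4 have 1 gene. The share without a gene was higher than among the other probe sets (Fisher's exact test, odds ratio 17.6, p = 3.37e-12). That test takes the probe sets as independent, though all were called on the same arrays, so its p does not measure the spread between arrays. The 4 with a gene, named here after their values were seen, read DLEU2 (-1.06), LRPPRC (-0.54), GOLGA4 (-0.67) and AKAP9 (-0.87). The brightest probe sets of the same genes were at 0.01, -0.03, 0.02 and -0.08 and did not pass, so the values do not describe these genes as a whole. These 29 probe sets had a median log2 difference of -0.89 and were also all below the control arrays in the comparison of metastin-10 with control peptide under control siRNA, at a median of -0.70, of which part may come from their choice on the same control arrays. The human Alu control probe set, which reads a repeat common in unspliced RNA, was at 14.13 ± 0.08 (SD, n = 3) with control siRNA and control peptide, 13.94 ± 0.06 in the arrays labelled GPR54 siRNA with control peptide, 14.05 ± 0.08 with control siRNA and metastin-10, and 13.99 ± 0.06 in the remaining group.

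At 1 probe set per gene, no gene passed between the siRNA labels with control peptide, and 2321 probe sets had an unadjusted p under 0.05. The 5 genes with the smallest p, none past the threshold, were SMG1P5 (-0.64), CALCB (0.43), DEPDC1-AS1 (0.49), FTX (-1.21) and BMS1P2 (-0.55), of which SMG1P5 passed with the replicate block (adjusted p = 0.0229). None of the RNA interference machinery genes was called (14 genes, median -0.03) and none of the interferon response genes, a class that transfected RNA can induce (31 genes, median -0.02). Camera called the hypoxia and glycolysis list higher (median 0.11, adjusted p = 2.01e-07), with 0 members called over all probe sets or adjusted over the list alone, and the call was lost at an adjusted p of 0.13 with an estimated correlation. No other list was called, and adjusted over the list alone 1 NF-kB gene rose and no member of another list passed. The count of probe sets was 51 with the replicate block, 87 with replicate 3 as a batch block and 0 with replicates 1 and 2 only. It was 10 and 5 without control siRNA, control peptide replicates 1 and 2, 18 and 19 without control siRNA, metastin-10 replicates 1 and 2, 10 and 3 without replicates 2 and 3 of the arrays labelled GPR54 siRNA with control peptide, and 18 and 44 without replicates 2 and 3 of those with metastin-10.

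With metastin-10, the arrays labelled GPR54 siRNA had higher levels of many genes that were lower with metastin-10 under control siRNA, the same control siRNA, metastin-10 arrays being used for both. SCGB1D1 was 1.85 ± 0.13 (log2, SE) higher, ADM 1.84 ± 0.10, COXFA4L2 1.77 ± 0.14 and SPAG4 1.55 ± 0.09. The microRNA host gene MIR210HG (1.29), NDRG1 (1.24), the nuclear receptor gene RORA (1.24), DPYSL4 (1.24), ANKRD37 (1.22), MMP10 (1.21), ALDOC (1.14) and CYP1A1 (1.09) followed. Of RORA, the other 7 probe sets were dimmer and did not pass, and the other probe set of ANKRD37, also dimmer, was at 0.03. Lower were ADAMTS5 (-0.98), TAGLN (-0.78), ANKRD1 (-0.72), CCN2 (-0.63), MYEOV (-0.57), the synaptotagmin gene SYT16 (-0.56), AMIGO2 (-0.56), KCNJ16 (-0.56), CLDN1 (-0.52), SAMD4A (-0.52), ADAMTS1 (-0.50) and the cAMP-activated exchange factor RAPGEF3 (-0.48). KISS1R was 1.03 higher (95% interval 0.82 to 1.24, adjusted p = 0.000391) in the arrays labelled as its knockdown. In all 316 probe sets passed, 288 higher and 28 lower, which came to 191 genes higher and 14 lower.

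Of the hypoxia and glycolysis genes 13 rose and 0 fell in this comparison, with a median of 0.60 (adjusted p = 5.62e-33, and adjusted p = 0.00101 with an estimated correlation), and 24 rose adjusted over the list alone. Among the epithelial junction and keratin genes the keratin gene KRT19 (0.59) and MUC1 (0.57) rose and CLDN1 fell, and camera called the list higher (median 0.11, adjusted p = 0.032, and adjusted p = 0.701 with an estimated correlation). The smooth muscle markers were called lower (median -0.14, adjusted p = 0.0035, and adjusted p = 0.0748 with an estimated correlation), again with TAGLN as the member that fell. Adjusted over the list alone, 4 epithelial genes rose and 1 fell, and 2 smooth muscle markers fell. Other lists were not called, though LOXL2 (0.91), S100A4 (0.58) and VIM (0.55) rose among the mesenchymal transition genes, CXCR4 (0.98) among the adhesion genes, the cell cycle inhibitor gene CDKN1A (0.58) among the p53 targets, ID2 (0.51) among the TGF-beta targets, and VLDLR (0.64) and DDIT3 (0.47) among the stress genes. STC2 (0.85) and VEGFA (0.79) rose in their lists as well. Adjusted over the list alone, 4 mesenchymal transition, 5 stress, 2 NF-kB, 2 angiogenesis, 1 adhesion, 1 kisspeptin signalling and 1 apoptosis gene rose. In the same tally 3 p53 targets rose and 1 fell, 1 immediate early gene rose and 3 fell, 2 oestrogen response genes rose and 1 fell, 1 rose and 1 fell in each of the matrix protease and TGF-beta lists, and the remaining lists had 0.

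This comparison shares the control siRNA, metastin-10 arrays with the metastin-10 comparison under control siRNA. Of the 211 lower and 288 higher probe sets 135 were in common, where independent lists would share 1.11. The fold changes correlated at r = -0.78 across genes, against -0.50 simulated for unchanged groups, and their covariance was -0.023 against -0.0072 simulated. The simulation took the arrays as independent, which leaves out deviations shared by same-numbered arrays. The 3 shared arrays cannot be divided with at least 2 on each side, so part of the excess may come from them. The count was 602 with replicate 3 as a batch block, 396 with replicates 1 and 2 only, and 57 with only the 2 groups compared. It was 136 and 149 without replicate 1 or 2 of the control siRNA, metastin-10 group, and 129 and 138 without replicate 1 or 2 of the arrays labelled GPR54 siRNA with metastin-10.

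The interaction tested whether the metastin-10 effect differed between the siRNA labels. At 1 probe set per gene, SCGB1D1 (1.60 ± 0.19, log2, SE), ADM (1.52 ± 0.14), COXFA4L2 (1.49 ± 0.19) and SPAG4 (1.21 ± 0.13) had the largest positive differences, and ANKRD1 (-1.08 ± 0.14) and TAGLN (-0.98 ± 0.13) the negative ones, while over all called probe sets the largest difference was 2.13. G0S2 (1.13), MMP10 (1.11), CYP1A1 (1.05), DPYSL4 (1.05), MIR210HG (0.99), ALDOC (0.95), the activin subunit gene INHBE (0.92) and the stress gene DDIT4 (0.91) followed. The mitophagy genes BNIP3 (0.75) and BNIP3L (0.72) passed as well. KISS1R was at 0.89 with an adjusted p of 0.04996, a call that was lost when any 1 array was left out, except replicate 3 of the arrays labelled GPR54 siRNA with metastin-10 (adjusted p from 0.0369 to 0.198). In all 28 probe sets passed, 25 higher and 3 lower, which came to 21 genes.

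The hypoxia and glycolysis list had a median difference of 0.45 (4 higher, 0 lower, and 15 higher adjusted over the list alone), and camera called it (adjusted p = 7.75e-26, and adjusted p = 0.00244 with an estimated correlation). The epithelial junction and keratin list (median 0.14, adjusted p = 0.027) and the stress list (median 0.06, adjusted p = 0.0371) had no called member, and each had an adjusted p of 0.694 with an estimated correlation. With the replicate block the stress list lost its camera call (adjusted p = 0.0542). Adjusted over the list alone, 1 epithelial gene was higher and 1 lower, as in the matrix protease list, and 1 immediate early gene was higher and 2 lower. There 2 mesenchymal transition genes were higher, as was 1 gene each of the stress, kisspeptin signalling, adhesion, p53, NF-kB, oestrogen and angiogenesis lists, and 1 TGF-beta target and 2 smooth muscle markers were lower. All 25 higher probe sets of the interaction were lower with metastin-10 under control siRNA, from which the interaction is in part computed. The count was 45 with the replicate block, 73 with replicate 3 as a batch block and 2 with replicates 1 and 2 only. It was 10, 8 and 10 without control siRNA, control peptide replicates 1, 2 and 3, 10 and 9 without control siRNA, metastin-10 replicates 1 and 2, 14, 10 and 10 without replicates 1, 2 and 3 of the arrays labelled GPR54 siRNA with control peptide, and 9 and 6 without replicates 1 and 2 of those with metastin-10.

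The metastin-10 effect under control siRNA and the difference between the siRNA labels with control peptide are both taken against the control siRNA, control peptide arrays. Across genes they correlated at r = 0.25, below the 0.50 simulated for unchanged groups against those arrays, and their covariance was 0.0046 against 0.0072 simulated. The simulation took the arrays as independent. Deviations shared by same-numbered arrays could lower the simulated covariance, so no conclusion is drawn from the shortfall. Of 211 and 29 lower probe sets 21 were in common, where independent lists would share 0.11, and 19 of the 21 have no gene in the annotation used. The 3 control arrays cannot be divided with at least 2 on each side, so part of this overlap may come from them. The siRNA label differences under the 2 peptides, which share no arrays, correlated at r = 0.17 across genes.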

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

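The results listed here are those in which the metastin-10 effect differed between the siRNA labels by the interaction test. The tests on exchanged labels, on a transfection without effect, on the background level and on the replicate 3 arrays, the batch block included, were chosen only after the result was seen.

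The interaction called 28 probe sets. The log2 differences of the named genes were 1.60 for SCGB1D1, 1.52 for ADM, 1.49 for COXFA4L2, 1.21 for SPAG4, 1.13 for G0S2, 1.11 for MMP10, 1.05 for CYP1A1, 1.05 for DPYSL4, 0.99 for MIR210HG, 0.95 for ALDOC, 0.92 for INHBE, 0.91 for DDIT4, 0.89 for KISS1R, 0.75 for BNIP3 and 0.72 for BNIP3L, with -1.08 for ANKRD1 and -0.98 for TAGLN. The median differences of the called lists were 0.45 for hypoxia and glycolysis, 0.14 for epithelial junction and keratin and 0.063 for unfolded protein and amino acid stress genes. Of 100 splits of the arrays by peptide within each siRNA arm, 5 called as many probe sets, the real one included. The highest other split called 278, several times the real count, which points to a structure of the samples. Of the 99 other splits, 8 kept the real grouping of the control siRNA arm, and the 4 that called as many were all among these, while the 91 that broke it called 0 probe sets each. A split that keeps this grouping keeps the effect from which the interaction is in part computed, so the count of splits does not settle whether chance can be excluded. Of the 4, those with 278, 97 and 42 put the replicate 3 arrays labelled GPR54 siRNA on one side and the one with 35 did not, while 2 more that did so called 21 and 18. With replicate 3 as a batch block the real grouping called 73. The epithelial and stress lists each had an adjusted p of 0.694 with an estimated correlation, so only the hypoxia and glycolysis list kept its call there.

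KISS1R was lower with metastin-10 under control siRNA and not lower in the arrays labelled GPR54 siRNA, so the absence of metastin-10 effects there is not tied to a measured loss of the receptor mRNA. An exchange of group labels together with a knockdown seen at this probe set would leave 2 groups low, but 1 of the 4 group means lay more than 0.5 below the highest, which argues against that case only. A probe set at background would hide a fall, but this one lay at percentile 89.4 of all probe sets and moved by 0.88 in one group. With correct labels and cultures otherwise alike, a transfection without effect would leave equal metastin-10 effects under both siRNAs. The interaction of the hypoxia and glycolysis list (median 0.45, adjusted p = 0.00244 by camera with an estimated correlation) argues against that case only. The list median for metastin-10 was -0.39 under control siRNA and 0.02 in the arrays labelled GPR54 siRNA. Another difference of the control siRNA, metastin-10 cultures or arrays could give this with a transfection without effect, which the test cannot exclude. What stays open, untested here, is that case and a siRNA that acted on the protein or earlier than the harvest. A wrong label of a single group, and an exchange of labels with a knockdown that this probe set does not show, stay open too.

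Hypoxia and glycolysis genes were lower with metastin-10 under control siRNA. A shift shared by the replicate 3 arrays cancels between the groups, since replicate 3 is present once in each group. The list median was below 0 between the same-numbered arrays of each replicate, the highest being -0.31, so the fall did not rest on replicate 3 alone. The brightness of the genes is argued against, since 0% of 10000 lists matched on mean level had a median as low. With the beta-actin 3 prime minus 5 prime difference as a covariate the list median stayed at -0.37 (adjusted p = 0.00646 by camera with an estimated correlation). That difference averaged 0.65 ± 0.32 (SD, n = 3) with control peptide and 0.60 ± 0.25 with metastin-10 under control siRNA. It varied mostly by replicate number, so the covariate could hardly move the median and does not decide on RNA integrity. Sparser cultures in that group might lower oxygen use and raise YAP and TEAD targets, of which ANKRD1 and CCN2 were seen to be higher. The median of 19 other targets was 0.0053, with 10 of them above 0. They ranged from -0.35 for RBMS3 to 0.49 for CCN1 (limma adjusted p = 0.0535 for CCN1). Sparser cultures cannot be told apart from an effect of metastin-10. A response to the peptide, which the design names, remains open, as does any other difference of the cultures or arrays of that group.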

How the results depend on the processing

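The covariate of poly-A spike level, replicate 3 as a batch block and the use of replicates 1 and 2 only were chosen only after the result was seen. For metastin-10 in the arrays labelled GPR54 siRNA, the count of probe sets was 0 under every alternative run. No call of a named gene or list, and not the KISS1R difference between the siRNA labels, changed direction under any alternative. The directions of the other called probe sets were not compared one by one. Of 88 calls of named genes, all 88 kept their call with the replicate block, the batch block, quantile normalization, array weights and 1 probe set per gene, 87 with a trended and robust prior, 83 with the poly-A covariate, 76 with median centring, 51 with replicates 1 and 2 only, and from 57 to 76 without 1 array. With only the 2 groups compared 35 of 71 kept it, and 29 of 88 were at least 2-fold. Where an alternative tests fewer probe sets or fewer arrays, or sets a higher minimum, that is part of the change; for the others the cause was not tested. The arrays give no signal over background here, so it is unknown how far dim probe sets limit the counts.

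The counts below are for metastin-10 under control siRNA, the siRNA label with control peptide, the siRNA label with metastin-10 and the interaction, in that order, which were 234, 29, 316 and 28. With the replicate block they were 422, 51, 504 and 45. Over all 4 groups, same-numbered arrays deviated together in 14 of 18 pairs by a correlation over 0.1, and 9 of 12 arrays correlated best with their own number, a hint from the data and not from the design. In the 3 comparisons whose arrays were taken as paired, the block added BMF and the p53 list (adjusted p = 0.564 with an estimated correlation and no block) for metastin-10 under control siRNA and SMG1P5 between the siRNA labels with control peptide, and it changed no other call of a named gene or list. With replicate 3 as a batch block the counts were 532, 87, 602 and 73, with a trended and robust prior 397, 56, 525 and 88, and with array weights 495, 130, 2016 and 250. Of the 2016, 1364 were higher and 652 lower (67.7% higher, against 91.1% of the 316). With a minimum of 2-fold they were 18, 8, 27 and 14. With only the 2 groups compared the first 3 were 77, 9 and 57. The last 3 were 10, 597 and 55 among probe sets above percentile 50 of mean level, and 0, 526 and 64 above percentile 75. Quantile normalization gave 45 for the interaction, replicates 1 and 2 only gave 0 for the siRNA label with control peptide and 2 for the interaction, and 1 probe set per gene gave 0 for the siRNA label with control peptide.

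The preset camera test called 4, 1, 3 and 3 lists in the same order. With an estimated correlation it called 1, 0, 1 and 1, and fry called 2, 0, 2 and 1. Quantile normalization gave 5 lists for the interaction, and replicates 1 and 2 only gave 5 for the siRNA label with metastin-10. The hypoxia and glycolysis list between the siRNA labels with control peptide, at a median of 0.11, lost its call with an estimated correlation (adjusted p = 0.13) and with fry (adjusted p = 0.0887). With the replicate block the stress list in the interaction had an adjusted p of 0.0542, and CXCR4 and VEGFA passed there (adjusted p = 0.0482 and 0.0416), as did BMF between the siRNA labels with metastin-10 (adjusted p = 0.0223). For these contrasts the numbers were not taken to pair the arrays, a choice that the values do not settle.

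Leaving out 1 array at a time gave from 71 to 263, 3 to 44, 129 to 332 and 6 to 32 probe sets, and from 3 to 6, 1 to 2, 2 to 4 and 1 to 5 lists. For metastin-10 in the arrays labelled GPR54 siRNA it gave 0 to 0 probe sets and 0 to 1 lists, the 1 without replicate 3 of those arrays with metastin-10. For the interaction, 1 list was called without control siRNA, control peptide replicate 2 and without replicate 1 or 2 of the arrays labelled GPR54 siRNA with metastin-10, and 5 without replicate 1 of those with control peptide, whose omission also gave 2 lists between the siRNA labels with control peptide. The hypoxia and glycolysis medians ranged from -0.43 to -0.35, 0.08 to 0.17, 0.56 to 0.64 and 0.35 to 0.54. The KISS1R difference between the siRNA labels over both peptides ranged from 0.49 to 0.70, with a highest exact permutation p of 0.0498, in a test that ignores the peptide.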

Other observations

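The test on the Alu probe set was chosen only after the result was seen, as were the genes named next and the list of cilia genes, whose own test was set before its value was computed, while the comparison of its median with an error was added after.

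Further genes lower with metastin-10 under control siRNA were picked singly from the called ones. The log2 fold changes were -0.66 for CFAP126, -0.68 for RSPH1, a component of the radial spoke, -0.55 for ODAD4 and -0.59 for DNALI1, an axonemal dynein light chain. The secretoglobin SCGB2A1 was at -0.62 and STC1, which encodes stanniocalcin-1, at -0.60. All of these passed the limma threshold for metastin-10 under control siRNA. In the arrays labelled GPR54 siRNA with metastin-10 the first 4 genes were higher than under control siRNA, by 1.04, 0.69, 0.61 and 0.59. The genes were picked as low in the same control siRNA, metastin-10 arrays, so part of this difference is built in. The metastin-10 effect in the arrays labelled GPR54 siRNA uses none of those arrays. There CFAP126 was at 0.15, RSPH1 at -0.03 and ODAD4 at -0.11.

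Whether cilia genes are lower as a set was tested on 96 genes, taken by family prefix followed by a number and including FOXJ1, a rule that left DNALI1 out. The rule also admitted the antisense and divergent transcripts CFAP65-AS1 (0.23), CFAP95-DT (0.14), CFAP100-DT (0.14) and DNAH17-AS1 (0.35). It set no minimum level, and members such as CFAP299 and CFAP161 had mean levels of 2.43 and 2.68, where a fall may be hidden. The median of the set is limited by such entries. The set had a median of 0.015 and 5 members that fell, DNAI7, CFAP96, CFAP126, RSPH1 and ODAD4. It was not called by camera (adjusted p = 0.831). The 91 members that did not pass had a median of 0.018. By the test as set beforehand, a median of 0 or above counts against a fall beyond the called members. The standard error of the median, added later and taken with the genes as independent, was 0.026. The sign of the median is therefore uncertain, and leaving out the called members, all of which fell, also raises it. The matter stays undecided. FOXJ1, the transcription factor of motile cilia, was at -0.44 (adjusted p = 0.209).

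The probe sets lower in the arrays labelled GPR54 siRNA with control peptide mostly have no gene in the annotation used. A candidate explanation is more unspliced or nuclear RNA in the control siRNA, control peptide arrays, under which the human Alu control probe set should be higher there. It was, on each of those 3 arrays against each of the 3 others, with a mean difference of -0.19 for the siRNA label minus control. Complete separation of 3 against 3 has a two-sided exact p of 0.1 at best without the pairing by number. Exchanges within the 3 pairs taken for this comparison cannot reach a p that low, so chance stays open. The same probe sets were also lower with control siRNA and metastin-10, at a median of -0.70 that is in part built in by their choice on the same control arrays, and there the Alu probe set was lower between all 3 same-numbered arrays (group means of 14.05 against 14.13) though the 2 groups overlapped, and a biological explanation was not tested.

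For the pairwise comparisons there are 10 splits of 6 arrays, too few for a share under 0.05. Metastin-10 under control siRNA called 234 probe sets in the real split (1 of the 10 with as many) and 0 at most in any other. The siRNA label with metastin-10 called 316 (1 of 10) against 0 at most, and with control peptide 29 (1 of 10) against 0 at most. In the comparisons taken as paired, 3 of the other splits also put all same-numbered arrays on opposite sides, and these called 0 as well. For metastin-10 in the arrays labelled GPR54 siRNA all 10 splits called 0.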
